A study of Homo sapiens with 4 samples.

How the data were processed

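RNA of 585A1 human induced pluripotent stem cells, untreated or irradiated with THz light at 0.5 MV/cm, was measured in 4 libraries, 2 per group, and groups and replicate numbers were taken from the sample labels. Per the labels' protocols, cDNA was made from 10 ng of total RNA with an anchored oligo-dT primer and a strand-switching primer for Nanopore sequencing. That text also speaks of myoblasts as the source of the RNA, whereas each sample's own labels name 585A1 cells, and the latter were used. The values analysed were whole-number counts per gene symbol, deposited by the authors without normalization as 1 table of 35238 symbols. Per the submitters' processing notes the authors used edgeR, with no version given. The base caller, aligner, counting program, genome build and annotation are not given in the sources used here, so no coordinates are printed. Priming at the poly(A) tail favours 3' ends and polyadenylated RNA, long reads that end early lose 5' ends, and amplification or sequencing can favour some lengths and GC contents. How reads shared by near-identical genes or by overlapping genes were assigned, and whether strand was used, is likewise not given in the sources used here, so genes of that kind are uncertain.

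The table held 454135 counts. Totals were 102808 and 106853 in the controls and 61841 and 182633 in the THz libraries, with 9738, 10059, 7676 and 11299 genes at 1 count or more. A count of 0 allows up to 3 counts, or 29.18, 28.08, 48.51 and 16.43 CPM in these libraries. CPM were computed from library totals, and means ± SD are over the 2 libraries of a group. Ratios of summed counts pool the libraries of a group, so the deeper library weighs more, and they can differ from ratios of mean CPM. Intervals for ratios of summed counts are exact 95% intervals for counting error alone.

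Genes were tested in R 4.3.3 with edgeR 4.0.16. Those kept by filterByExpr (minimum count 10, minimum total 15) numbered 1731 and held between 78.0% and 80.1% of each library's counts. Libraries were scaled by TMM (factors 0.981 to 1.01), a quasi-likelihood model with the group as its single term was fitted with the defaults of that version, and p-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The common dispersion was 0.0100, a biological coefficient of variation of 10.0%, with 58.7 prior degrees of freedom, so the spread of a gene rested mainly on that of the other genes. The median dispersion by DESeq2 was 0.129. The median SE of a log2 fold change was 0.37, and 0.20 for genes with a mean of at least 50 counts.

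Before the data were examined, 22 gene lists, the tests and the alternatives were fixed. The lists were pluripotency, germ layer markers, motor neuron differentiation, zinc, iron, copper and calcium handling, heat shock, unfolded protein response, oxidative stress, p53 targets, immediate early genes, cell cycle, nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, cholesterol synthesis, glycolysis, skeletal myoblast and fibroblast markers, ZNF-named genes and replication-dependent histones. The 14 lists with at least 5 tested members were compared with all other tested genes by limma 3.58.1 camera on log2 CPM (prior count 2) with its preset correlation, and also by camera with an estimated correlation and by fry. For the others, summed counts are given.

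Named genes followed a rule fixed at the same time. It took genes past the adjusted threshold whose groups did not overlap (there were 0). It then filled each direction to 10 with the smallest unadjusted p under 0.05 among genes with a mean of at least 10 counts and groups that did not overlap. It added up to 4 members per list, first those passing over the list alone and then by unadjusted p, 12 genes named in advance (POU5F1, SOX2, NANOG, LIN28A, MT1X, MT2A, FTH1, FTL, HSPA1A, CDKN1A, FOS and EGR1) and the 5 genes with the most counts. GEMIN7 lies outside this rule. The result of 1 gene that the rule names is not reported here.

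The test was checked on 10 simulated sets with the depth of these libraries and the spread that edgeR estimated, each gene drawn independently. With no gene changed, 62 to 95 genes per set had an unadjusted p under 0.05 (a mean of 4.49%) and 2 of the 10 sets gave a call. With 200 changed genes, 4.29% of calls were false. A 1.5-fold rise of the oxidative phosphorylation list was recovered in 10 of 10 sets. The independent draws leave out correlation between its members, which camera estimated at 0.0785, so recovery of lists may be lower in real data.

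Alternatives were size factors by median of ratios, library totals alone, no filter, at least 10 counts in every library, DESeq2 1.42.0, the edgeR exact test, limma voom, the replicate number as a block with and without a correction for GC content and length, thinning to the smallest library, omission of mitochondrially encoded and ribosomal protein genes, other thresholds, and leaving out each library. For lists they were the other set tests, the block, a prior count of 0.5, median-of-ratios scaling and leaving out each library. Fits without a library or after thinning filtered genes anew, so the tested members of a list can differ between fits. Thinning was 1 random draw. Added after the data were seen were the newer quasi-likelihood settings, the corrections for GC content and length together and each alone, the joint correction for lists, and the estimated correlation of camera with each library left out. Planned pseudocounts for normalized values were not needed for counts, and the planned older quasi-likelihood settings proved to be the default of this edgeR version. Transcript length and GC content were medians over the transcripts of each gene in GENCODE release 29, matched by symbol for 27963 symbols and for 1713 (99%) of the tested genes. That release may differ from the authors' annotation.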

Results

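The data were gene counts from 4 libraries of 585A1, a human induced pluripotent stem cell line kept in a defined medium under self-renewal conditions. Cells of 2 libraries were untreated, and cells of the other 2 were irradiated with terahertz (THz) light, electromagnetic pulses between microwaves and infrared, at a field of 0.5 MV/cm. The title of the series names intracellular metal ions, so genes that handle zinc, iron, copper and calcium were among the groups examined. Each library was cDNA made by strand switching from 10 ng of total RNA with Nanopore primers. The libraries were shallow: the controls held 102808 and 106853 counts and the THz libraries 61841 and 182633, a 2.95-fold range. One count was therefore worth between 5.475 and 16.17 CPM (counts scaled to the library total), and a count of 0 allowed up to 48.51 CPM in THz replicate 1 and 16.43 CPM in THz replicate 2. Of 35238 gene symbols, 14562 had at least 1 count and 1731 had enough counts to be tested. Such floors and the intervals on sums of counts cover counting error only, since reads were not tagged as single molecules.

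Pluripotency genes were counted in all 4 libraries, and none of those tested passed the test between the groups. Cytosolic ribosomal protein genes took 22.2% and 22.6% of the counts in the controls and 22.8% and 24.7% in the THz libraries. RPL41 alone had 9814 ± 454 CPM in the controls and 10460 ± 1161 in THz (SD, n = 2). The pluripotency factor POU5F1 had 47 and 52 counts in the controls and 42 and 108 in the THz libraries, or 472 ± 20.9 CPM against 635 ± 62.1 CPM (SD, n = 2). SOX2, its partner on DNA, had 24 and 12 counts against 6 and 32. NANOG had 23 and 21 against 15 and 28, and LIN28A, an RNA-binding protein of pluripotent cells, had 26 and 32 against 31 and 52. Fold changes were 1.31 for POU5F1 (95% interval 0.950 to 1.79), 0.873 for SOX2 (0.500 to 1.53), 0.861 for NANOG (0.519 to 1.43) and 1.28 for LIN28A (0.844 to 1.94). A 2-fold change lay outside the intervals of POU5F1, NANOG and LIN28A, and a 2-fold lower level of SOX2 was at the edge of its interval. These intervals rest on the spread estimated by edgeR, and a larger spread would widen them. The log2 fold change of SOX2, -0.20, was 0.40 without control replicate 1 and 0.04 without THz replicate 1, and that of NANOG, -0.22, was 0.17 without THz replicate 2. That of LIN28A, 0.36, was 0.05 without THz replicate 1 and 0.81 without THz replicate 2. Of 14 tested genes of the pluripotency list, 8 had higher and 6 lower values in THz, with a median log2 fold change of 0.05, and none passed, whether adjusted over all genes or adjusted over the list alone. That median ran from -0.04 without control replicate 2 to 0.23 without THz replicate 2, over 15 genes each, since such fits filtered genes anew. SFRP2, a secreted modulator of Wnt signalling, stood at 238 ± 20.5 CPM in controls and 385 ± 119 CPM in THz, and L1TD1, an RNA-binding protein of pluripotent cells, at 1623 ± 125 and 1389 ± 300 CPM (SD, n = 2).

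**Figure D1:**
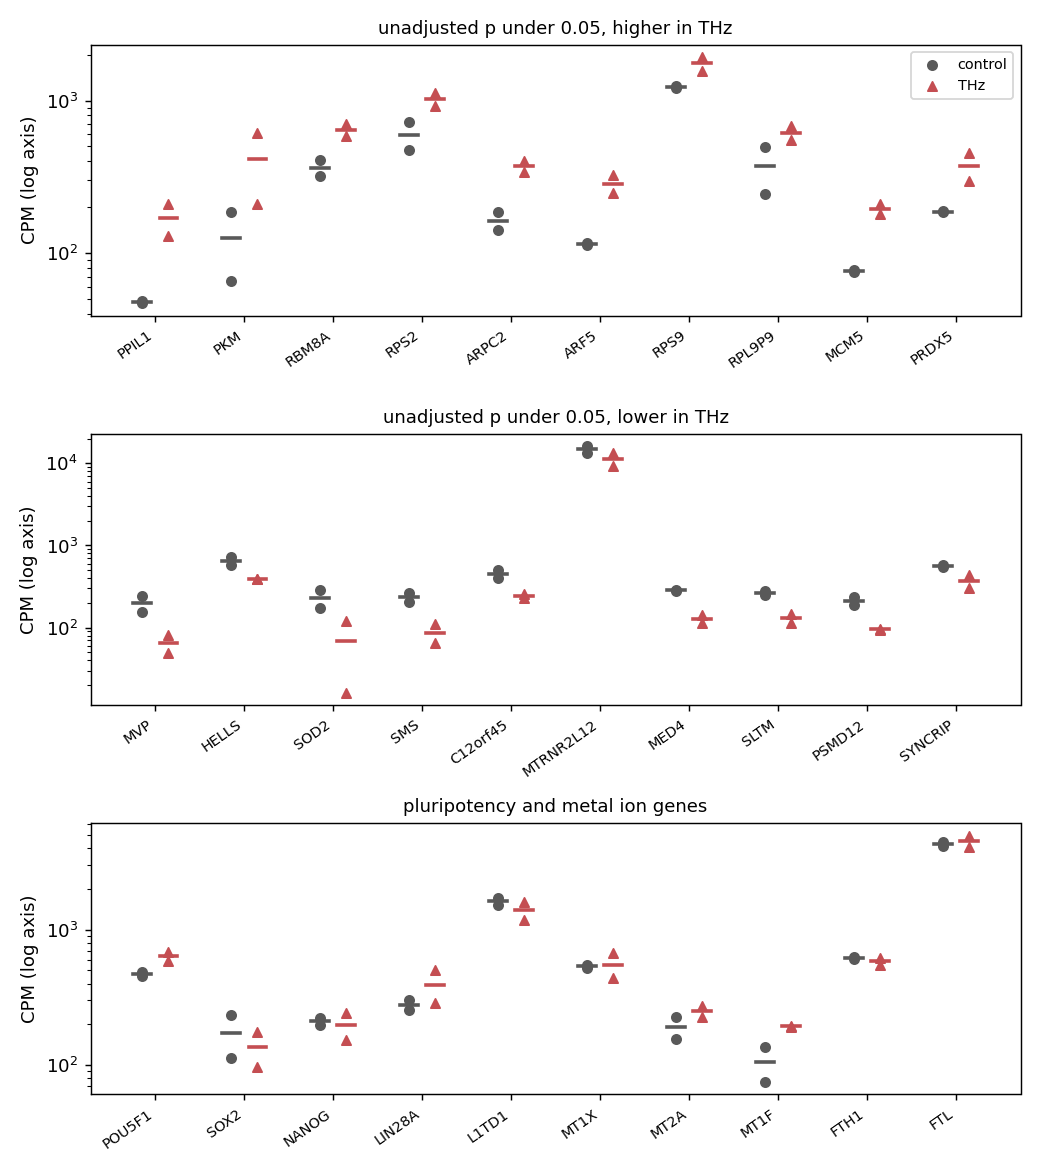
CPM on a log axis of 30 genes in each of the 4 libraries, with circles for control libraries, triangles for THz libraries and a bar for each group mean (n = 2). The upper panels hold the 10 genes per direction with the smallest unadjusted p among those with a mean of at least 10 counts whose groups did not overlap, none of which passed the adjusted threshold, and the lower panel holds pluripotency and metal ion genes such as POU5F1 (472 against 635 CPM) and FTL (4319 against 4544 CPM).

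The comparison of THz with control asked which transcripts differed after irradiation. Ranked by unadjusted p among genes with a mean of at least 10 counts whose groups did not overlap, those with higher values in THz included PPIL1, a spliceosomal prolyl isomerase (47.7 ± 1.30 CPM in controls, 169 ± 55.7 in THz, SD, n = 2), and PKM, the pyruvate kinase that ends glycolysis (125 ± 84.4 and 411 ± 287). RBM8A, of the exon junction complex, stood at 363 ± 63.9 and 641 ± 84.0 CPM, and the ribosomal protein genes RPS2 and RPS9 at 599 ± 172 and 1021 ± 135 CPM and at 1231 ± 20.1 and 1751 ± 258 CPM. By the same ranking, lower values in THz were found for MVP, the major vault protein (199 ± 62.0 and 65.3 ± 23.8 CPM), HELLS, a chromatin remodeller (655 ± 106 and 388 ± 0.471 CPM), and SOD2, the mitochondrial superoxide dismutase (233 ± 81.3 and 68.3 ± 73.7 CPM). SMS, the spermine synthase, stood at 233 ± 40.9 and 87.1 ± 31.7 CPM, and the mediator subunit MED4 at 286 ± 5.68 and 128 ± 20.6 CPM. None of these genes passed the test.

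By edgeR's quasi-likelihood test, 0 of the 1731 genes changed at a Benjamini-Hochberg adjusted p under 0.05, 0 were higher and 0 lower, and the smallest adjusted p was 0.175. At an unadjusted p under 0.05 there were 115 genes, 59 with higher and 56 with lower values in THz, where 86.6 would be reached by chance. Of these, 33 also differed at least 2-fold, 16 with higher and 17 with lower values. DESeq2 called 0 genes (14 at an unadjusted p under 0.05), the edgeR exact test called 1 (99), and limma voom called 1 (128). The 2 THz libraries lay on one side of both controls for 625 genes (36.1%), where chance gives 33.3%. With 2 libraries a group there are 3 splits, so no exact permutation test of a single value could give a p below 0.333. On simulated data of the same depth and the spread estimated by edgeR, 200 of 1731 genes were changed. The test recovered 17.9% of genes changed 1.5-fold, 54.4% at 2-fold, 87.4% at 3-fold and 95.7% at 4-fold. A larger spread would lower these shares. Among simulated genes with a mean of at least 50 counts, 93.9% of 2-fold changes were recovered. The 95% interval of the fold change excluded a 2-fold change for 897 genes (51.8%), and for 369 of the 380 genes with a mean of at least 50 counts. Such intervals also use the spread estimated by edgeR, and a larger one would widen them. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

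Among the 10 genes of smallest unadjusted p with higher values in THz, a mean of at least 10 counts and groups that did not overlap, the log2 fold changes were 1.91 (SE 0.54) for PPIL1, 1.47 (SE 0.42) for PKM, 0.85 (SE 0.24) for RBM8A, 0.72 (SE 0.21) for RPS2 and 0.53 (SE 0.17) for RPS9. ARPC2, of an actin-nucleating complex, had 1.14 (SE 0.34), the small GTPase ARF5 1.23 (SE 0.39), the replicative helicase subunit MCM5 1.29 (SE 0.45) and the peroxiredoxin PRDX5 0.89 (SE 0.33). RPL9P9, a pseudogene whose reads are hard to tell from those of its parent gene, had 0.76 (SE 0.26). Its value was 0.32 without control replicate 1 and 1.38 without control replicate 2, with 25 and 53 counts in the controls. Adjusted p-values of these 10 genes (edgeR, Benjamini-Hochberg) lay between 0.175 and 0.571. In the other direction, MVP had -1.46 (SE 0.45), HELLS -0.76 (SE 0.24), SOD2 -1.37 (SE 0.44), SMS -1.28 (SE 0.41), MED4 -1.10 (SE 0.36) and C12orf45 -0.88 (SE 0.29). SLTM, a regulator of transcription, had -1.11 (SE 0.38), the proteasome subunit PSMD12 -1.16 (SE 0.41) and the RNA-binding protein SYNCRIP -0.70 (SE 0.25). Adjusted p-values of the genes with lower values lay between 0.299 and 0.543. MTRNR2L12, a nuclear gene that resembles the mitochondrial large ribosomal RNA and can share its reads, had the most counts of all genes named, 14780 ± 1951 CPM in controls and 11250 ± 2910 in THz (SD, n = 2), a log2 fold change of -0.43 (SE 0.14). It was -0.20 without THz replicate 2, -0.27 without control replicate 2 and -0.68 without THz replicate 1, and THz replicate 1 (13310 CPM) was level with control replicate 1 (13400 CPM). GEMIN7, a member of the SMN complex, was chosen after its values were seen: it had 2 and 0 counts in the controls and 10 and 19 in the THz libraries, a ratio of 12.4 with an exact counting interval of 3.15 to 108. Its log2 fold change was 6.84 without control replicate 1, 2.60 without control replicate 2 and 3.33 without THz replicate 1. Its adjusted p was 0.175 by the quasi-likelihood test (edgeR, Benjamini-Hochberg), and it passed by the edgeR exact test (adjusted p = 0.00851) and with the newer quasi-likelihood settings (adjusted p = 0.0472), but not by DESeq2 or limma voom, with adjusted p-values from 0.00851 to 1 over the alternatives that add no term to the model. PKM and SOD2 differed within a group as well, PKM by 185 against 65.5 CPM between the controls and SOD2 by 1 against 22 counts between the THz libraries. PKM passed with an adjusted p of 0.00621 (edgeR) without control replicate 1 and of 5.7e-05 without THz replicate 2, and SOD2 with 0.0413 and 0.022 in the same fits. Without control replicate 2 and without THz replicate 1, the log2 fold change of PKM was 0.89 and 0.75 (adjusted p 0.908 and 0.885) and that of SOD2 -0.93 and -0.94 (adjusted p 0.992 and 0.885). In the fits that passed, these were 2.35 and 2.25 for PKM and -1.69 and -3.78 for SOD2.

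**Figure D2:**
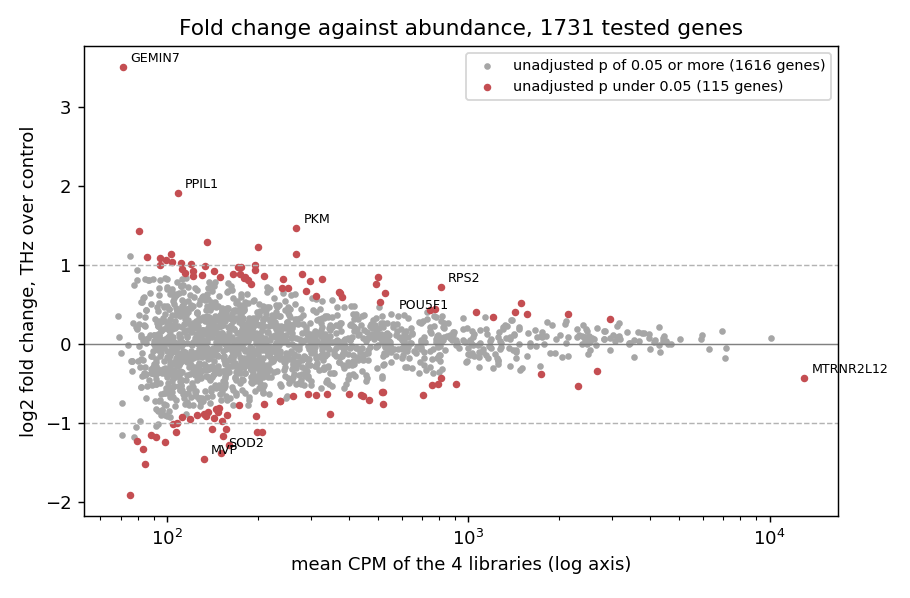
Log2 fold change of THz over control for the 1731 tested genes against the mean CPM of the 4 libraries on a log axis, with dashed lines at a 2-fold change. The 115 genes at an unadjusted p under 0.05 are in red and none passed the adjusted threshold, and the spread of fold changes narrows as CPM grows.

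Of the genes that handle metal ions none passed the test. The medians of the zinc, iron and calcium lists moved when a library was left out, which could also change the genes tested. Of the 7 tested zinc genes, 6 had higher and 1 a lower value, with a median log2 fold change of 0.20. The median was 0.06 over 9 genes without control replicate 1 and 0.10 over 8 without THz replicate 2. After thinning to the smallest library it was -0.03 over 5 genes. The tested zinc genes were largely metallothioneins, small proteins that bind zinc and copper: MT1F stood at 105 ± 43.4 CPM in controls and 193 ± 1.70 in THz, MT1E at 90.4 ± 17.8 and 109 ± 62.7, MT2A at 190 ± 48.8 and 250 ± 35.6, and MT1X at 539 ± 19.0 and 552 ± 164 (SD, n = 2). The metallothionein genes are near-identical copies, so their reads can be split between them, and the log2 fold changes of MT1E and MT1X, 0.48 and 0.12, were -0.52 and -0.35 without THz replicate 2. Of the 10 tested iron genes, 8 had higher and 2 lower values, with a median of 0.18. It was 0.35 over 10 genes without control replicate 2, 0.09 over 9 without THz replicate 2 and 0.04 over 6 after thinning. Over the 6 genes with at least 10 counts in every library it was 0.01. The ferritin genes FTH1 and FTL, which store iron and also have near-identical pseudogenes, stood at 615 ± 16.9 and 584 ± 48.7 CPM and at 4319 ± 205 and 4544 ± 595 CPM. Their fold changes were 0.961 (95% interval 0.710 to 1.30) and 1.03 (0.849 to 1.25), and with a correction for GC content and length the log2 fold change of FTL, 0.04, was -0.09. PCBP2, an RNA-binding protein that also delivers iron, had a log2 fold change of 0.64, LYRM4 and CISD1, of iron-sulfur clusters, 0.56 and 0.52, and GLRX5 0.42. Without THz replicate 2, LYRM4 had 0.09 and CISD1 0.13, against 0.76 and 0.69 without THz replicate 1. Without control replicate 1, GLRX5 had 0.20 and PCBP2 0.92, against 0.68 and 0.39 without control replicate 2. Of the 14 tested calcium genes, 9 had higher and 5 lower values, with a median of 0.09. It was -0.02 over 15 genes without control replicate 1 and 0.04 over 14 without control replicate 2. Without THz replicate 1 it was 0.04 over 15 genes, and after thinning 0.17 over 11. Camera's direction for calcium turned to down without control replicate 1 and without THz replicate 2. CALM2, a calmodulin gene, had -0.36, the chaperone CALR 0.33, S100A11 0.36 and SRI 0.28. For copper, 3 genes were tested, SOD1 (0.15), COX17 (0.03) and ATOX1 (-0.03), too few for a test of the list, and summed counts of its 13 members gave a ratio of 1.08 (exact counting interval 0.932 to 1.25). With limma's camera and its preset correlation, the adjusted p was 0.288 for zinc, 0.278 for iron and 0.817 for calcium, and 0 members of these lists passed when adjusted over the list alone.

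Mitochondrially encoded genes had lower and nuclear genes of the respiratory chain and of the ribosome mostly higher values in THz, and none of these lists passed. Of 12 tested mitochondrially encoded genes, 10 had lower values, with a median log2 fold change of -0.23. The ATP synthase gene MT-ATP6 had -0.51 (SE 0.20), the cytochrome oxidase genes MT-CO3, MT-CO1 and MT-CO2 had -0.37, -0.33 and -0.18, and the complex I gene MT-ND2 had -0.33. MT-ATP6 and MT-CO1 had -0.18 and -0.19 without THz replicate 2, and -0.71 and -0.44 without THz replicate 1. MT-CO3 had -0.21 without control replicate 1 and -0.53 without control replicate 2. The mitochondrially encoded genes took 2.25% and 2.36% of the counts in the controls and 2.20% and 1.87% in the THz libraries, so THz replicate 1 lay close to the controls and THz replicate 2 below them. Of 77 nuclear genes of oxidative phosphorylation, 51 had higher and 26 lower values, with a median of 0.08. NDUFB5 had 0.98 (SE 0.40), ATP5I 0.41 (SE 0.17), COX7A2 0.34 and COX6C 0.36. Of 80 cytosolic ribosomal protein genes, 63 had higher and 17 lower values, with a median of 0.08, among them RPSA (0.47), RPS29 (0.17) and RPS27A (-0.05). Camera gave an unadjusted p of 0.0304 and an adjusted p of 0.249 for the mitochondrially encoded list, and adjusted p-values of 0.318 for oxidative phosphorylation and 0.278 for the ribosomal proteins. Without THz replicate 1, the shallowest library, all 3 lists passed with adjusted p-values of 0.0441, 0.0176 and 0.00286 at the preset correlation. That fit keeps 1 THz library. No call was made there with camera's own estimate of the correlation. That version tests on the few residual degrees of freedom of the libraries. It could hardly have passed any list, so it cannot decide on these 3 lists. Without THz replicate 2, their adjusted p-values by camera were 0.812, 0.876 and 0.812, and the medians of the nuclear lists were -0.03 and -0.01.

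**Figure D3:**
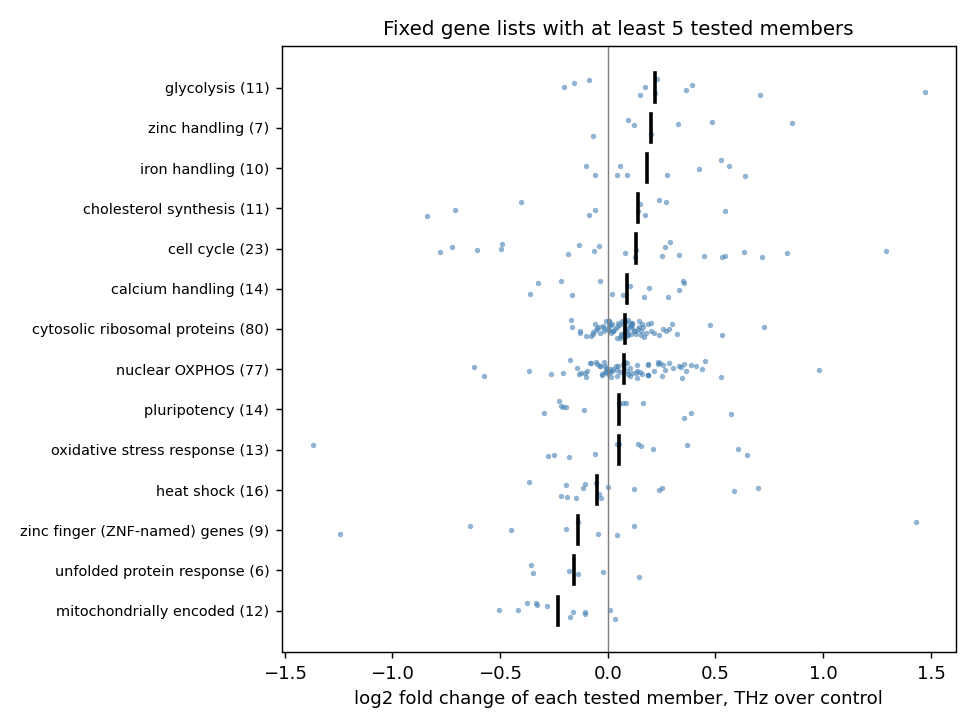
Log2 fold change, THz over control, of each tested member of the 14 lists with at least 5 tested members (a point per gene, a bar at the median, the number of tested members after the name). Medians lie between -0.23 for the mitochondrially encoded genes and 0.22 for glycolysis, and no list passed the adjusted threshold.

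Of the 11 tested genes of glycolysis, 8 had higher and 3 lower values in THz, with a median log2 fold change of 0.22. Beside PKM, GAPDH had 0.39 (SE 0.15), the mutase PGAM1 0.71 (SE 0.37, with 0.21 without control replicate 1 and 1.44 without control replicate 2) and the enolase ENO1 0.23 (SE 0.17, with 0.07 without control replicate 2). PKM was the 1 member that passed when adjusted over the list alone (adjusted p = 0.00642, edgeR), against 0 over all genes. The median was 0.05 over 13 genes without control replicate 2 and 0.37 over 12 without control replicate 1. Camera gave glycolysis an unadjusted p of 0.0355 and an adjusted p of 0.249. Over the 14 lists tested, camera called 0 with its preset correlation (2 at an unadjusted p under 0.05). With an estimated correlation it called 0 (0 at an unadjusted p under 0.05, smallest adjusted p = 0.833 with an estimated correlation). That version tests on the few residual degrees of freedom of the libraries, so hardly any list could pass. The unadjusted p of glycolysis by camera rose from 0.0355 to 0.158 there, although its estimated correlation was negative (-0.0483). The fry test, which asks whether the genes of a list move one way on balance, called 0 (1 at an unadjusted p under 0.05, glycolysis), with a smallest adjusted p of 0.248.

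Fold changes moved with the GC content of the transcripts. Across the 1713 tested genes with an annotated transcript, which are not independent replicates, Spearman's rho between log2 fold change and GC content was 0.289. It was 0.206, 0.148, 0.271 and 0.251 for the 4 pairs of a THz and a control library, and -0.103 and -0.0871 for the pairs within the control and the THz group. The median log2 fold change was -0.10 over the 571 tested genes poorest in GC, 0.01 over the 571 in the middle and 0.13 over the 571 richest in GC. Of the 115 genes at an unadjusted p under 0.05, 40 with higher values were among the 571 richest and 30 with lower values among the 571 poorest in GC. With a correction for GC content and transcript length, 0 genes changed by edgeR (86 at an unadjusted p under 0.05), as with a correction for GC content alone (85) or for length alone (110). The medians were then 0.14 for glycolysis, 0.10 for zinc, 0.15 for iron, 0.02 for oxidative phosphorylation, 0.01 for the ribosomal proteins and -0.21 for the mitochondrially encoded genes. For transcript length, rho was -0.146, with -0.126 between the THz libraries themselves.

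**Figure D4:**
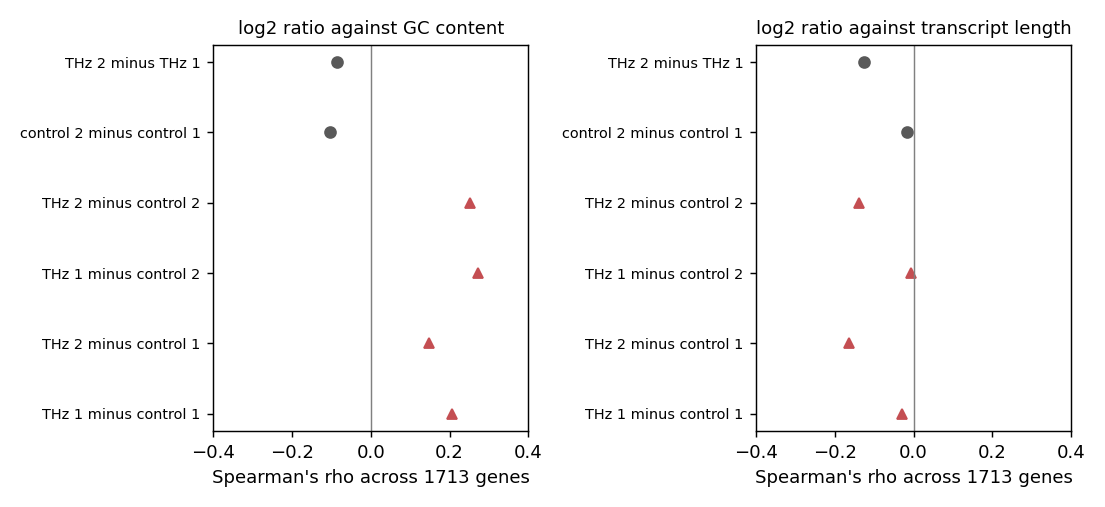
Spearman's rho, across 1713 genes, between the log2 ratio of each pair of libraries and the GC content (left) or length (right) of the transcripts, with triangles for a THz against a control library and circles for pairs within a group. For GC content the 4 triangles lie between 0.148 and 0.271 and the circles at -0.103 and -0.0871.

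No stress response list passed the test, and several of its best known genes were near the limit of detection. HSPA1A, the inducible heat shock protein, had 0 counts in all 4 libraries, which by counting error alone allows up to 16.43 CPM in the deepest. How reads shared by near-identical genes were assigned is not given, so a count of 0 may not bound its expression. The immediate early genes FOS (0 and 1 counts in controls, 0 and 1 in THz) and EGR1 (1 and 0, 0 and 1) and the p53 target CDKN1A (4 and 2, 2 and 4) were at or near the limit of detection. Of the 16 tested heat shock genes, 6 had higher and 10 lower values. The median of this list was -0.05, or -0.18 without THz replicate 2 and 0.01 without control replicate 1, and its mean 0.03, with camera's direction down (adjusted p = 0.817). HSP90AA1 stood at 1331 ± 43.1 and 1173 ± 10.0 CPM, HSPB1 at 138 ± 2.97 and 193 ± 67.5, FKBP4 at 72.0 ± 35.7 and 136 ± 60.0 and CACYBP at 591 ± 24.3 and 513 ± 5.83 (SD, n = 2). Of 6 tested genes of the unfolded protein response, 1 had a higher and 5 lower values (median -0.16, adjusted p = 0.624 by camera), with log2 fold changes of -0.36 for HSP90B1, -0.35 for ATF4, -0.18 for PDIA3 and -0.14 for HSPA5. That median was 0.07 without control replicate 1, -0.32 without control replicate 2 and -0.07 without THz replicate 2. Of 13 tested genes of the oxidative stress response, 8 had higher and 5 lower values (median 0.05, or -0.03 without THz replicate 2, adjusted p = 0.817 by camera). SOD2 was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0265, edgeR), against 0 over all genes, while TKT had 0.64 (SE 0.24), GPX1 0.60 (SE 0.38) and TXN -0.18 (SE 0.17). Among p53 targets, 2 genes were tested, RPS27L (-0.31) and CCNG1 (0.13), and RPS27L had 0.04 without THz replicate 2. The p53 targets summed to 1508 and 1479 CPM in the controls and to 1472 and 1177 CPM in THz replicates 1 and 2, so the ratio of pooled counts of 0.838 (exact counting interval 0.714 to 0.985) rested on THz replicate 2. The immediate early genes summed to 185 and 290.1 CPM in the controls and 323 and 170 CPM in THz, so the libraries of each group differed by more than the group means (238 and 247 CPM), and the ratio of pooled counts was 0.875 (0.580 to 1.32).

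Of 23 tested cell cycle genes, 14 had higher and 9 lower values in THz (median 0.13, adjusted p = 0.318 by camera), and 0 passed when adjusted over the list alone. The median was 0.02 over 26 genes without THz replicate 1 and 0.21 over 29 without control replicate 1. MCM5 and GINS2, both of the replicative helicase, had 1.29 and 0.72, while HMGB2 and the checkpoint gene BUB3 had -0.61 and -0.72, the latter -0.31 without control replicate 2 and -1.70 without THz replicate 2, and GINS2 had 0.31 without control replicate 2 and 1.26 without control replicate 1. The histone gene HIST1H4C stood at 2447 ± 337 and 2555 ± 183 CPM (SD, n = 2), and summed counts of 89 replication-dependent histone genes gave a ratio of 1.09 (exact counting interval 0.983 to 1.21). Of 11 tested genes of cholesterol synthesis, 6 had higher and 5 lower values. The median of this list was 0.14, or -0.05 over 12 genes without THz replicate 2 and 0.05 over 12 without control replicate 2. The mean of the 11 genes was -0.05, with camera's direction down (adjusted p = 0.624). HMGCS1 had -0.71, CYP51A1 -0.84, ACAT2 -0.40 and IDI1 0.54, and all but CYP51A1 moved with single libraries: HMGCS1 from -0.11 without control replicate 2 to -1.96 without THz replicate 2, ACAT2 from -0.08 without THz replicate 1 to -1.42 without THz replicate 2, and IDI1 to -0.95 without THz replicate 2. Of 9 tested ZNF-named genes, 3 had higher and 6 lower values (median -0.14, adjusted p = 0.443 by camera), with -1.24 for ZNF3, -0.64 for ZNF688, -0.45 for ZNF326 and 1.43 for ZNF414. The median was -0.02 over 10 genes without control replicate 2 and -0.24 over 11 without THz replicate 2. Single libraries moved the values of single genes too. ZNF414 had 0.43 without control replicate 2 and 6.79 without control replicate 1 (its counts in the controls were 9 and 0). Without THz replicate 2, ZNF3 had -0.44, ZNF688 0.07 and ZNF326 -1.18, and ZNF326 had -0.20 without THz replicate 1.

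Markers of other cell types were low in both groups. Summed CPM of 25 germ layer markers were 296 ± 21.6 in controls and 269 ± 77.7 in THz (SD, n = 2), a ratio of summed counts of 0.816 (exact counting interval 0.562 to 1.18), and KDR was the 1 gene tested (log2 fold change 0.24). THz replicate 1 (323 CPM) lay above both controls, so that ratio rested on THz replicate 2 (214 CPM). For motor neuron differentiation the sums were 195 ± 14.9 and 209 ± 24.6 CPM, a ratio of 1.02 (0.663 to 1.59). Skeletal myoblast markers, included because the extraction text of the labels speaks of myoblasts, summed to 210 ± 7.77 and 166 ± 17.4 CPM, a ratio of 0.760 (0.481 to 1.20). Fibroblast markers summed to 272 ± 12.8 and 214 ± 62.9 CPM, a ratio of 0.707 (0.470 to 1.06), with TAGLN at a log2 fold change of -0.71. Here too THz replicate 1 (259 CPM) was close to the controls (263 and 281 CPM) and THz replicate 2 (170 CPM) below them. All ratios above pool counts, so the deeper library of a group weighs more. Ratios of mean CPM were 0.907 for germ layer markers and 1.07 for motor neuron differentiation. They were 0.789 for myoblast and 0.789 for fibroblast markers.

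Across tested genes, Pearson's r of log2 CPM was 0.925 between the controls and 0.919 between the THz libraries, and lay between 0.891 and 0.937 for pairs of a THz and a control library. Among genes with a mean of at least 50 counts it was 0.967 between the controls, 0.956 between the THz libraries and 0.952 to 0.964 between the groups. The counts of each pair differed by more than sampling noise, with a chi-square per degree of freedom of 1.35 and 1.36 within groups and of 1.32 to 1.59 between them. This cannot tell separate cultures from repeat preparations of the same RNA.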

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

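Chosen after the data were seen were the newer quasi-likelihood settings of edgeR, the corrections for GC content, for length and for both without the block, and the estimated correlation for lists with 1 library left out. The count of 0 changed genes held under median-of-ratios scaling, library totals alone, no filter, at least 10 counts in every library, DESeq2, omission of mitochondrially encoded and ribosomal protein genes, the corrections for GC content, for length and for both, and an adjusted threshold of 0.1. It became 1 with the edgeR exact test and with the newer settings (1 higher, GEMIN7, both times), 1 with limma voom (1 lower, MTRNR2L12) and 1 after thinning (1 higher, RPS2). The cause was not tested. At an unadjusted p under 0.05 and 2-fold, 33 genes were counted, 16 higher and 17 lower. Genes at an unadjusted p under 0.05 numbered 426 of 14562 with no filter, 68 of 1041 with at least 10 counts in every library, 68 of 1187 after thinning and 14 with DESeq2, against 115. Fewer or more genes tested account in part for the first 3. For DESeq2 the cause was not tested. Its median dispersion was 0.129, a different measure from the common dispersion of 0.0100 by edgeR.

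Replicate numbers were not shown to pair the samples: deviations of same-numbered libraries correlated at 0.0766 across genes. With the replicate block 2 genes were called (2 higher, GEMIN7 and PKM). With the replicate block and the GC and length correction 7 were called, 3 higher (GEMIN7, PKM and PPIL1) and 4 lower (MVP, SLC25A48, SOD2 and ZNF688). The block called 0 lists.

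Leaving out 1 library leaves a lone library that is assumed to vary like the other group. Between 0 and 3 genes were then called, with 0 to 1 higher and 0 to 2 lower, and 60 to 119 had an unadjusted p under 0.05. Of the 87 tested named genes, 62 had a log2 fold change that turned or moved by over 1.5 times without at least 1 of the libraries. Calls numbered 3 without control replicate 1 (MAB21L3, PKM and SOD2), 1 without control replicate 2 (ARIH1), 0 without THz replicate 1 and 3 without THz replicate 2 (APOL6, PKM and SOD2). Between 0 and 3 lists were called, the 3 without THz replicate 1, the library with 61841 counts, and 0 in each of these fits with an estimated correlation. Camera with an estimated correlation, fry, a prior count of 0.5, median-of-ratios scaling and the correction for GC and length called 0 lists. An estimated correlation leaves camera few degrees of freedom, with all libraries or with 1 left out, so its lack of calls says little.

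Of the 67 tested named genes that were not chosen by their p among all genes, 20 changed sign in at least 1 alternative (ATOX1, CACYBP, CCNG1, COX17, FTH1, FTL, HIST1H4C, HSPA5, IDI1, MT1E, MT1X, NANOG, PDIA3, RPL41, RPS27A, RPS27L, SOD1, SOX2, SRI and ZNF688), in 19 cases with all libraries and in 23 with 1 left out. The lowest Pearson's r between libraries was 0.891 over tested genes and 0.952 over those with a mean of at least 50 counts, where counting error is smaller. Depth limits the detection of small differences: at the spread estimated by edgeR, a 2-fold change was recovered in 54.4% of simulated genes. Among those with a mean of at least 50 counts it was recovered in 93.9%.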

Other observations

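The count of other splits of the libraries for genes and the match of ZNF-named genes on counts alone were set before their results were seen. The other tests here were chosen or tightened only after the result was seen: those of GC content and length across genes, of the mitochondrially encoded genes, of the corrections for GC content or length alone, of GEMIN7, of ZNF-named genes by length and GC content and by splits, and of all 22 lists against random lists. By the conditions first written, transcript length would have counted as a bias between the groups, and a part played by 1 library in the mitochondrial pattern as excluded.

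ZNF-named genes, most of which encode zinc finger transcription factors, summed to 7947 and 8638 CPM in the controls and 6743 and 6801 CPM in the THz libraries, over 556 genes of which 9 had enough counts to be tested singly. The ratio of mean sums was 0.817. The sum over the 33507 symbols that were not tested singly had a ratio of 0.916, so weakly counted genes were lower in THz as a whole. GEMIN7, at 19.5 and 0 CPM in the controls and 162 and 104 CPM in the THz libraries, lies where MARK4 and PPP1R37 are also annotated, whose summed CPM differed by -17.9 against 123 for GEMIN7. In the controls MARK4 and PPP1R37 summed to a mean of 28.8 CPM, so they could not have fallen by as much as GEMIN7 rose. The comparison therefore cannot decide on shared reads.

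The first pattern is the surplus of 115 genes at an unadjusted p under 0.05 and the trend of fold changes with GC content. The 3 splits of the 4 libraries are too few for a share under 0.05. The real split gave 115 genes and the highest other split, of replicates 1 against replicates 2, gave 85. That other split called 1 gene at an adjusted p under 0.05 by edgeR, against 0 for the real one. It also had 3 lists at an unadjusted p under 0.05 by camera, against 2. A GC content bias between the groups goes with rho of 0.289, which had the same sign in all 4 pairs of a THz and a control library. In size, rho was larger in each of these pairs than in either pair within a group. After correction for GC content alone, 85 genes had an unadjusted p under 0.05 by edgeR (72 of them among the 115), where 86.6 are reached by chance. After correction for length alone there were 110. The GC correction was fitted to these same libraries and removes such a trend whatever its cause. The fall to 85 is therefore no further support for a bias. Whether that trend came from preparation of the libraries or from irradiation stays open, since no batch is named in the labels, and transcript length (rho -0.146) cannot be told apart from a difference between single libraries, since the THz libraries differed from each other by -0.126.

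The second pattern is the lower values of mitochondrially encoded genes, with a median log2 fold change of -0.23 over 12 genes (bootstrap SD 0.08) in THz. The median was -0.21 (-0.2082) after correction for length and GC content, below the bound of -0.1 by more than that SD, so most of the lower value remained. That SD covers the spread over genes and not that between libraries, so such a bias is not excluded. After thinning to the smallest library the median was -0.23 (-0.2268) over 10 genes, also below the bound by more than that SD. Thinning leaves the expected ratios unchanged, so this value cannot speak on library size. Leaving out 1 library gave a median of at most -0.16 (-0.1645), within that SD of the bound, so a part played by 1 library cannot be told apart. An effect of irradiation on mitochondrial transcripts may also account for it, as an untested hypothesis, and the list did not pass the test.

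The third pattern is the lower sum of ZNF-named genes. Its ratio lay at percentile 0.14 of 10000 random lists matched on counts per gene, and at percentile 0.81 of lists matched also on transcript length and GC content. The ratio was thus lower than that of most matched lists in these libraries. The percentiles treat genes as independent and do not measure the spread between libraries. They therefore do not exclude a general loss of weakly counted genes, or a bias by length and GC content, as the whole cause. A coarser match on the same properties, run first, gave percentile 0.53. Of the 3 splits, too few for a share under 0.05, 1 gave a ratio as far from 1 as 0.817, the real one, and the highest other was 1.05. Against random lists matched in the same way, 1 of the 22 lists lay outside the central 95%, the ZNF-named genes, where 1.1 are expected by chance, so a shift of this family in irradiated cells may be no more than the extreme of 22 lists, with mitochondrially encoded genes at percentile 3.0 and glycolysis at 97.3.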
